A study of Arabidopsis thaliana with 12 samples.

How the data were processed

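RNA from 12 samples of whole Arabidopsis thaliana plants of the Columbia ecotype was measured on 1-colour Agilent arrays of a custom design, 1 array per sample. Per the labels, the plants were 4 days old, the untreated, Ky-2, salt and Ky-2 plus salt groups held 3 samples each, Ky-2 was given for 24 hours, and 100 mM NaCl for 2 hours. Ky-2 is an inhibitor of histone deacetylases, the enzymes that take acetyl groups off histone tails. The labels print the Ky-2 concentration as 1 M, which may have lost a prefix of the unit, so the dose is left open here. Titles and treatment fields name Ky-2 for every treated sample, while the description field of some samples carries another number after "Ky", so groups were taken from titles and treatments. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

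Per the file headers, the authors scanned the arrays and extracted each spot's intensity with Agilent Feature Extraction 10.7.3.1, which subtracted background and detrended the signal within each array and compared no arrays with each other. The deposited intensity columns used here were that processed signal, the mean signal and the median local background. The deposited table of values for the whole series holds log2 values, per their range and their correlation with the scanner signal. The submitters' processing notes name RMA and limma without a role or version. That table lists 20034 probes of 18199 loci, with medians between 10.14 and 10.17 in the 12 columns, and its values correlated with the scanner signal of the same array at r between 0.992 and 0.995 across probes. Its values were not centred and higher values meant higher signal, and the rule by which its probes were chosen is not given in the sources used here. Each array held 53459 spots that are not controls. Between 54.6% and 61.8% of the spots were well above background, the 75th percentile of the processed signal lay between 517 and 893 units, and no spot was saturated. The number of arrays, 3 per group, limits the precision.

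Control spots and outlier spots were left out, replicate spots of a probe were averaged on the log2 scale, and each value was set as log2 of the processed signal minus the 75th percentile of its array. The array design names 32781 loci with 1 probe each, of which 23459 were well above background on at least 3 of the 12 arrays and were tested. Locus names were matched to a gene table of the TAIR10.1 assembly, used for symbols only, and 32316 matched. The assembly behind the array design is not given in the sources used here, so no coordinates are printed. Probes not named by a locus, 8473 of them above background, stayed out of the comparisons.

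One model with 4 group means was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3, and empirical Bayes tests gave 5 comparisons. These were Ky-2 against untreated, salt against untreated, Ky-2 plus salt against salt, Ky-2 plus salt against Ky-2, and the interaction, which is the salt response with Ky-2 minus the salt response without it. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over the loci tested, and a gene was called at an adjusted p under 0.05. The text gives the number of calls that also moved at least 2-fold. A gene below background on every array of a group has only a bound there, so its fold is printed as "at least" and sets the bright group's mean against the lowest signal well above background on each dim array, or the gene's own signal where higher.

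Before the data were examined, 23 gene lists with 307 members were fixed, of which 293 were above background. Each list was tested in each of the 5 comparisons with limma's camera, which asks whether the members moved relative to the other genes, at a preset correlation of 0.01 between genes and with adjustment over all 115 tests. No call held when the correlation was estimated for each list, and the smallest adjusted p was then 0.127, so that value is printed beside each call. The 23 lists covered sodium and potassium transport, histone deacetylases, dehydration and ABA response, ABA metabolism, clade A PP2C phosphatases, PYR/PYL ABA receptors, stress transcription factors, proline and raffinose metabolism, reactive oxygen enzymes, heat shock, photosynthesis, cell cycle, seed maturation, pollen, root hair, secondary wall and xylem, jasmonate, salicylate and defence, early auxin response, ethylene, circadian clock, flavonoid and anthocyanin synthesis, and reference genes.

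The genes named in the text come from a rule fixed at the same time. It takes the 10 largest rises and 10 largest falls among called genes with a symbol whose groups did not overlap (8 of each for the interaction, with no condition on overlap), SOS1 and SOS3 whatever their values, and up to 4 members of each list with the smallest adjusted p where any passed. The text prints 209 of the 453 pairs of a gene and a comparison that the rule gives. All the largest rises and falls are printed, while list members were chosen for the text after their values were seen, some being passed over because an alternative ended their call. Symbols are those of the gene table, so that LTI65 is RD29B, HD1 is HDA19, SHY2 is IAA3, ERD5 is the proline dehydrogenase ProDH1, GEA6 is EM6, TT4 is chalcone synthase and EDS16 is ICS1.

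Replicate n of each group lay on slide n, except that replicate 3 of Ky-2 plus salt was alone on slide 4, and replicates 1 and 2 were scanned on one day and replicate 3 on another. Slide and scan day were therefore fitted as blocks, and scan day 1 was also fitted alone with 2 arrays per group. Scan day 2 held 1 array per group and each slide at most 1, which leaves no spread for a test. The alternatives fixed beforehand changed the background correction (normexp with an offset of 50), the normalization (quantile, median over detected probes), the source of the values, the filter on dim probes, the variance model, the samples in the fit, the replicate number and the slide as blocks, and left out each array in turn. Spike-in scaling, scan day and the omission of the 2 arrays that stood apart were added after seeing the data. The code was tested on simulated data. For Ky-2 against untreated, over 23457 genes, 52% of 50 genes changed 1.5-fold were recovered, 82% of those changed 2-fold and 94% of those changed 4-fold, while 7 unchanged genes were called. For the interaction these shares were 20%, 72% and 92%, with 14 unchanged genes called.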

Results

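Gene expression was measured in young Arabidopsis plants grown without treatment, with the histone deacetylase inhibitor Ky-2 for 24 hours, with 100 mM NaCl for 2 hours, or with both, on 3 arrays per group. Arrays of one group correlated at r between 0.985 and 0.994 across genes, and the highest correlation between arrays of different groups was 0.972. Of 23459 genes above background, the values of 69.4% did not overlap between the 3 Ky-2 and 3 untreated arrays, where chance gives 10%. The corresponding shares were 47.1% for salt against untreated, 68.2% for Ky-2 plus salt against salt and 50.7% for Ky-2 plus salt against Ky-2. Values below are log2 signals relative to the 75th percentile of each array, with standard errors from the limma fit, n = 3 arrays per group, and limma's Benjamini-Hochberg adjusted p.

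The first comparison asked what Ky-2 did in plants without salt. SOS1 (AT2G01980), the plasma membrane sodium exporter, rose from 0.53 ± 0.15 to 1.97 ± 0.06 (mean ± SD, n = 3), a log2 change of 1.43 ± 0.08 (SE, adjusted p = 2.2e-07). SOS3 (AT5G24270), the calcium sensor of the same pathway, rose by 0.50 ± 0.12 (adjusted p = 0.0038). The SOS3 call ended with normexp background correction, and its adjusted p lay between 8.2e-04 and 0.067 over 28 alternatives. The Ky-2 sample exceeded the untreated one for both genes on each of slides 1, 2 and 3, for SOS1 by 1.41, 1.63 and 1.25. The largest fitted rise among genes with a symbol was that of AGO5 (AT2G27880), an Argonaute protein that binds small RNAs, at 419-fold (above background on 2 of 3 untreated arrays). KNU (AT5G14010), a zinc finger repressor of floral stem cells, was at least 65.7-fold higher, the Pumilio RNA-binding protein PUM12 (AT5G56510) at least 52.5-fold, the arabinogalactan protein FLA20 (AT5G40940) at least 103-fold, the MADS-box factor AGL39 (AT5G27130) at least 34.4-fold and the potassium channel gene KT5 (AT4G32500) at least 50.3-fold. Metabolic genes among the largest rises were CYP81G1 (AT5G67310) at 155-fold (above background on 1 of 3 untreated arrays), the acyltransferase AACT1 (AT5G61160) at 147-fold (above background on 1 of 3 untreated arrays), the beta-glucosidase DIN2 (AT3G60140) at least 32.1-fold and the trehalose phosphate synthase TPS4 (AT4G27550) at least 34.7-fold.

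The largest fitted fall with Ky-2 among genes with a symbol was that of NdhL (AT1G70760), a subunit of the chloroplast NADH dehydrogenase-like complex, which was 105-fold lower. PnsL1 (AT2G39470), of the same complex, was 26.9-fold lower. Genes given below as "at least" may have fallen further than their bound. The auxin-induced growth genes SAUR22 (AT5G18050) and SAUR23 (AT5G18060) were at least 29.1-fold and at least 10.8-fold lower, the glucosinolate enzyme AOP2 (AT4G03060) 45.2-fold (above background on 1 of 3 Ky-2 arrays), the auxin repressor family member IAA32 (AT2G01200) at least 12.9-fold, the ethylene synthesis enzyme ACS8 (AT4G37770) at least 6.67-fold, and the receptor-like kinases CRK24 (AT4G23320) and CRK21 (AT4G23290) 28.4-fold (above background on 2 of 3 Ky-2 arrays) and at least 6.88-fold. The microRNA gene MIR841a (AT4G13564) was at least 4.58-fold lower. Without untreated replicate 1 the fall of SAUR22 was at least 45.5-fold, and that of AOP2 was at least 30.8-fold without Ky-2 replicate 1 and 26.7-fold without Ky-2 replicate 3. The 20 genes of largest change had standard errors of 0.11 to 0.61 on the log2 scale and adjusted p of at most 7.1e-05.

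Photosynthesis genes fell as a group with Ky-2. Of 17 members 16 fell and 1 did not pass, with the same counts adjusted over the list alone, among them the light-harvesting proteins LHCA1 (AT3G54890, log2 change -2.12 ± 0.16), LHCB3 (AT5G54270, -2.39 ± 0.20) and LHCB4.1 (AT5G01530, -2.34 ± 0.22). Photosynthesis genes had a median log2 change of -1.04 with camera adjusted p = 2.3e-05 and adjusted p = 0.52 with an estimated correlation. In the dehydration and ABA response list, 13 of 23 measured rose, 2 fell and 8 did not pass (the same adjusted over the list alone), among them COR15A (AT2G42540, 4.46 ± 0.26) and KIN2 (AT5G15970, 2.31 ± 0.08). Dehydration and ABA response genes had a median log2 change of 0.87 with camera adjusted p = 0.0082 and adjusted p = 0.53 with an estimated correlation. Cell cycle genes rose, among them CDKB2;1 (AT1G76540, 1.49 ± 0.09), CDKB1;1 (AT3G54180, 1.07 ± 0.07), the ribonucleotide reductase subunit TSO2 (AT3G27060, 1.07 ± 0.08) and the replication clamp PCNA1 (AT1G07370, 0.94 ± 0.06). In that list, 9 of 13 measured rose, 1 fell and 3 did not pass (the same adjusted over the list alone). Cell cycle genes had a median log2 change of 0.61 with camera adjusted p = 0.011 and adjusted p = 0.29 with an estimated correlation. Of the pollen genes, 3 of 4 measured rose and 1 did not pass (the same adjusted over the list alone). Those that rose were the actin ACT12 (AT3G46520, at least 1.6-fold higher), the tubulin TUA1 (AT1G64740, 1.31 ± 0.08) and BCP1 (AT1G24520, at least 3.81-fold higher). ACT12 and BCP1 were above background on 5 and 6 Ky-2 arrays and on 0 others, so they entered the test only through the Ky-2 arrays. VGD1, PPME1 and PGA4 stayed too dim to enter, which favours a rise of this list. Pollen genes had a median log2 change of 2.06, or 0.99 with dim members at their bounds, with camera adjusted p = 0.017 and adjusted p = 0.51 with an estimated correlation. Normexp background correction ended the call of ACT12 and that of the list (adjusted p = 0.147), whose adjusted p lay between 0.0092 and 0.51 over 19 alternatives.

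Among lists without a call in this comparison, the histone deacetylases themselves moved both ways, and 6 of 16 measured rose, 4 fell and 6 did not pass (the same adjusted over the list alone). Of all genes tested, 63.7% were called in this comparison, so these counts do not set the list apart. HDA18 (AT5G61070) changed by 2.26 ± 0.11, HDA14 (AT4G33470) by -2.27 ± 0.13, HD2C (AT5G03740) by 1.28 ± 0.09 and HDA6 (AT5G63110) by 0.84 ± 0.06. Of the sodium and potassium transport genes, 5 of 15 measured rose, 3 fell and 7 did not pass (the same adjusted over the list alone), with the endosomal exchangers NHX6 (AT1G79610) and NHX5 (AT1G54370) at 2.25 ± 0.10 and -1.28 ± 0.08 and the kinase SOS2 (AT5G35410) at -0.93 ± 0.08. DREB2C (AT2G40340) and DREB2B (AT3G11020), stress transcription factors, rose by 4.73 ± 0.37 and 3.21 ± 0.14, and in that list 6 of 21 measured rose, 5 fell and 10 did not pass (the same adjusted over the list alone). The peroxidase APX2 (AT3G09640) rose by 5.16 ± 0.09 and the mitochondrial chaperone HSP23.6-MITO (AT4G25200) by 4.52 ± 0.13. Of the genes often used as references, ACT8 (AT1G49240) rose by 0.81 ± 0.10 and GAPC1 (AT3G04120) by 1.15 ± 0.15.

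In all, limma called 14953 of 23459 genes between Ky-2 and untreated plants, 7188 higher and 7765 lower, and 5150 of them moved at least 2-fold, 2828 higher. The number past 2-fold was 3080 with normexp background correction, 3015 with normexp and quantile normalization and 3142 with the authors' processed values. The number called was 15884 with slide as a block, 15457 with scan day as a block and 13354 on scan day 1 alone. The split depended on the scaling. When arrays were scaled to their spike-in probes, with the replicate number as a block, 76.5% of the calls were higher instead of 48.1%, and the median of all genes moved from -0.05 to 0.34, so single changes are relative to the bulk of the genes.

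**Figure D1:**
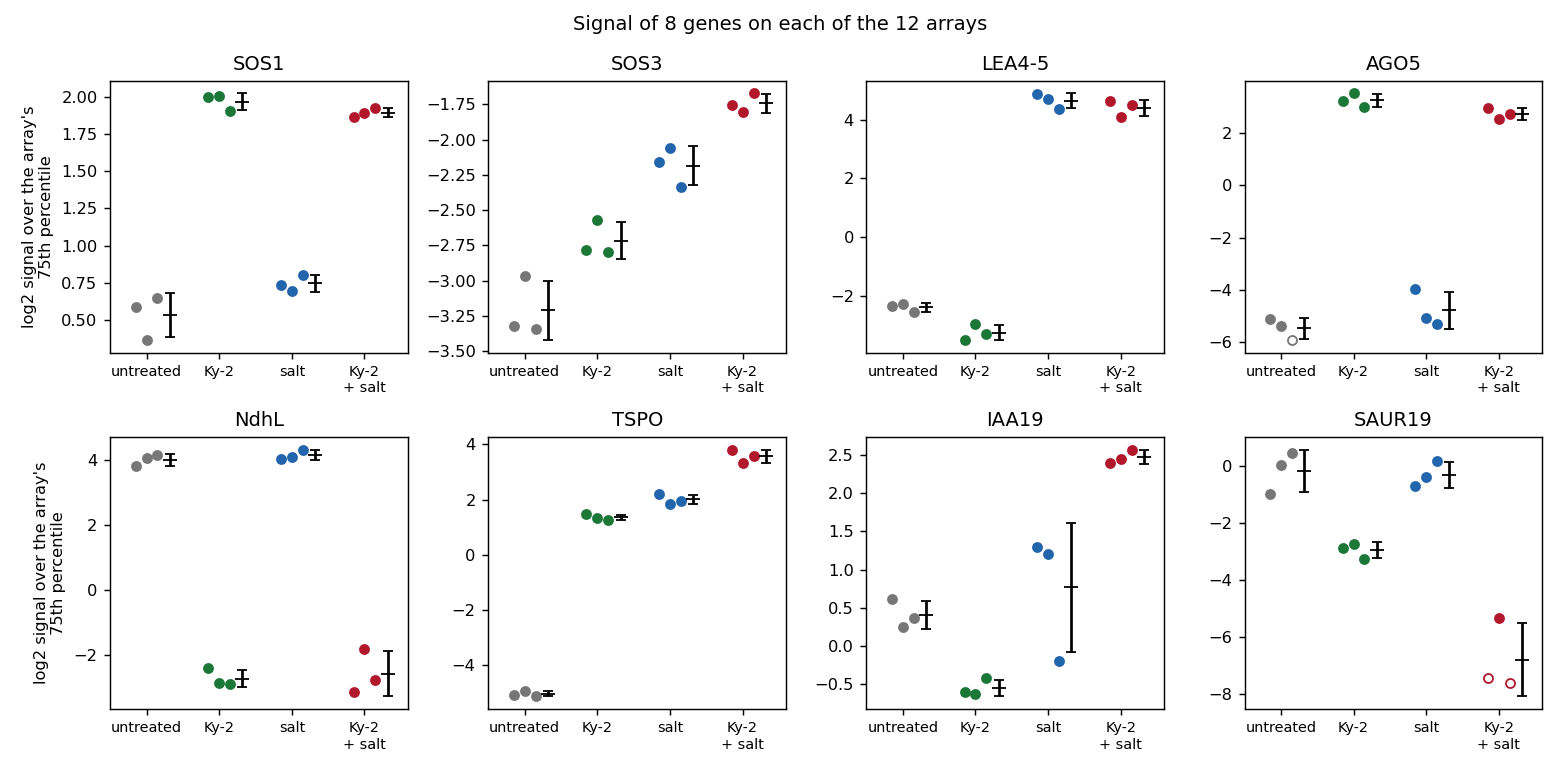
Signal of 8 genes on each of the 12 arrays, as log2 over the 75th percentile of the array (vertical axis, a separate scale per gene), by group (horizontal axis). Points are single arrays in order of replicate, open points are arrays on which the gene was not well above background, and bars show the mean and SD of 3 arrays. SOS1 was higher on both sets of Ky-2 arrays, LEA4-5 on both sets of salt arrays, and IAA19 rose with salt by 3.03 with Ky-2.

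The second comparison gave the response to 2 hours of NaCl in plants without Ky-2. TSPO (AT2G47770), a membrane protein induced by osmotic stress, was 133-fold higher and the late embryogenesis abundant protein LEA4-5 (AT5G06760) 131-fold higher. The transcription factors HSFA6B (AT3G22830), MYB102 (AT4G21440) and BHLH92 (AT5G43650) were 103-fold (above background on 2 of 3 untreated arrays), at least 22.2-fold and at least 20.7-fold higher. The dehydration gene LTI65 (AT5G52300) was 78.8-fold higher, the PP2C phosphatase HAI3 (AT2G29380) at least 34.8-fold, the carboxypeptidase-like scpl30 (AT4G15100) at least 13.6-fold, the kinase MAPKKK21 (AT4G36950) 50.9-fold (above background on 1 of 3 untreated arrays), and the gibberellin-regulated GASA3 (AT4G09600) at least 9.36-fold. Among the largest falls, the ethylene synthesis enzyme ACS4 (AT2G22810) was at least 5.57-fold lower, the iron-deficiency factor bHLH39 (AT3G56980) 10.5-fold (above background on 1 of 3 salt arrays), the RADIALIS-like RL1 (AT4G39250) at least 3.2-fold, and the signal peptide gene CLE4 (AT2G31081) at least 3.49-fold. LBD14 (AT2G31310) was at least 4.87-fold lower, the ABA receptor PYL6 (AT2G40330) 8.08-fold, and the lateral root factor GATA23 (AT5G26930) 7.77-fold (above background on 1 of 3 salt arrays). XTH33 (AT1G10550), a cell wall enzyme, was 7.73-fold lower, the disease resistance homologue HR2 (AT3G50460) 7.7-fold (above background on 2 of 3 salt arrays), and CYP705A20 (AT3G20110) 6.87-fold. Some of these folds rest on single arrays. Without salt replicate 2, scpl30 was at least 8.64-fold, BHLH92 at least 12.2-fold and MAPKKK21 32.2-fold higher. Without salt replicate 3, BHLH92 was at least 31.4-fold and MAPKKK21 81.6-fold higher. Without salt replicate 1, scpl30 was at least 23.9-fold higher and bHLH39 at least 5.34-fold lower, and without untreated replicate 1 MAPKKK21 was at least 20.9-fold higher. These 20 genes had standard errors of 0.11 to 0.74 on the log2 scale and adjusted p of at most 0.0033. SOS3 rose by 1.03 ± 0.12 (adjusted p = 1.4e-04), while SOS1, at 0.21 ± 0.08, did not pass (adjusted p = 0.062). SOS1 was higher in the salt sample than in the untreated one on each of slides 1, 2 and 3, it passed in 6 alternatives, among them slide as a random block and the omission of untreated replicate 3, but not with slide as a fixed block, and its adjusted p lay between 0.023 and 0.3 over 29 alternatives.

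All 23 dehydration and abscisic acid (ABA) response genes rose with salt, with the same count adjusted over the list alone, among them the dehydrin LTI30 (AT3G50970, 4.0 ± 0.14) and the cold and ABA inducible KIN2 (1.9 ± 0.08). Dehydration and ABA response genes had a median log2 change of 2.61, or 2.4 with dim members at their bounds, with camera adjusted p = 8.0e-24 and adjusted p = 0.13 with an estimated correlation. All 9 clade A PP2C phosphatases, which hold ABA signalling in check, rose too, with HAI1 (AT5G59220) at 5.12 ± 0.20, ABI2 (AT5G57050) at 2.63 ± 0.12 and HAB1 (AT1G72770) at 2.0 ± 0.13. Clade A PP2C phosphatases had a median log2 change of 2.63, or 2.33 with dim members at their bounds, with camera adjusted p = 2.4e-10 and adjusted p = 0.13 with an estimated correlation. The ABA receptors that act on those phosphatases moved the other way, and 1 of 10 measured rose, 6 fell and 3 did not pass (the same adjusted over the list alone), with PYL4 (AT2G38310) at -1.81 ± 0.08 and PYR1 (AT4G17870) at -1.42 ± 0.08. PYR/PYL ABA receptors had a median log2 change of -0.68 with camera adjusted p = 0.0031 and adjusted p = 0.13 with an estimated correlation. NCED3 (AT3G14440), the enzyme that limits ABA synthesis, rose by 4.24 ± 0.36, although the ABA metabolism list as a whole was not called (adjusted p = 0.077).

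Among stress transcription factors 13 of 21 measured rose and 8 did not pass (the same adjusted over the list alone), with HB-7 (AT2G46680) at 2.89 ± 0.12 and ABF3 (AT4G34000) at 1.36 ± 0.06. Stress transcription factors had a median log2 change of 1.68 with camera adjusted p = 2.3e-08 and adjusted p = 0.51 with an estimated correlation. Of the jasmonate genes, 10 of 19 measured rose and 9 did not pass (12 higher and 0 lower adjusted over the list alone), among them the synthesis enzymes LOX2 (AT3G45140, 1.32 ± 0.14), AOC2 (AT3G25770, 1.59 ± 0.18) and AOC1 (AT3G25760, 1.46 ± 0.21). Jasmonate genes had a median log2 change of 1.04 with camera adjusted p = 9.3e-06 and adjusted p = 0.52 with an estimated correlation. Of the clock genes 7 of 12 measured rose, 1 fell and 4 did not pass (the same adjusted over the list alone), with PRR5 (AT5G24470) at 1.77 ± 0.12 and FKF1 (AT1G68050) at 1.36 ± 0.18. The 1 fall did not pass when any array was left out except untreated replicate 3 and Ky-2 replicates 1 and 3. Circadian clock genes had a median log2 change of 0.44 with camera adjusted p = 0.0018 and adjusted p = 0.13 with an estimated correlation. Flavonoid genes fell, and 9 of 12 measured fell and 3 did not pass (the same adjusted over the list alone), with LDOX (AT4G22880) at -1.33 ± 0.11, DFR (AT5G42800) at -1.19 ± 0.13 and the chalcone synthase TT4 (AT5G13930) at -0.85 ± 0.06. Without untreated replicate 1 or Ky-2 plus salt replicate 2, 1 flavonoid gene rose. Flavonoid and anthocyanin synthesis genes had a median log2 change of -0.56 with camera adjusted p = 0.0031 and adjusted p = 0.52 with an estimated correlation. In the seed maturation list 6 of 13 measured rose and 7 did not pass (the same adjusted over the list alone). Seed maturation genes had a median log2 change of 2.23, or 1.92 with dim members at their bounds, with camera adjusted p = 0.0031 and adjusted p = 0.52 with an estimated correlation. That median was 1.37 without salt replicate 3 and 3.04 without salt replicate 2, and 1.25 on scan day 1 against 4.33 on scan day 2. GEA6 (AT2G40170), a late embryogenesis protein, was at least 9.31-fold higher, while 9 of the list's 10 storage protein and oleosin genes were at least 4-fold higher in salt replicate 3 than on any other array. The raffinose pathway enzyme GolS2 (AT1G56600) rose by 5.35 ± 0.51, and among ion transporters the vacuolar exchangers NHX2 (AT3G05030), CAX1 (AT2G38170) and CAX3 (AT3G51860) changed by 1.11 ± 0.06, -2.0 ± 0.18 and -1.87 ± 0.19.

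Between salt and untreated plants 7785 genes were called, 3294 higher and 4491 lower, and 1768 moved at least 2-fold, 1065 of them higher. The number past 2-fold was 859 with normexp background correction, 876 with normexp and quantile normalization and 996 with the authors' processed values. The number called was 8785 with slide as a block, 8465 with scan day as a block and 4602 on scan day 1 alone. With spike-in scaling and the replicate number as a block, 3937 genes were called and 52.4% of them were higher instead of 42.3%.

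**Figure D2:**
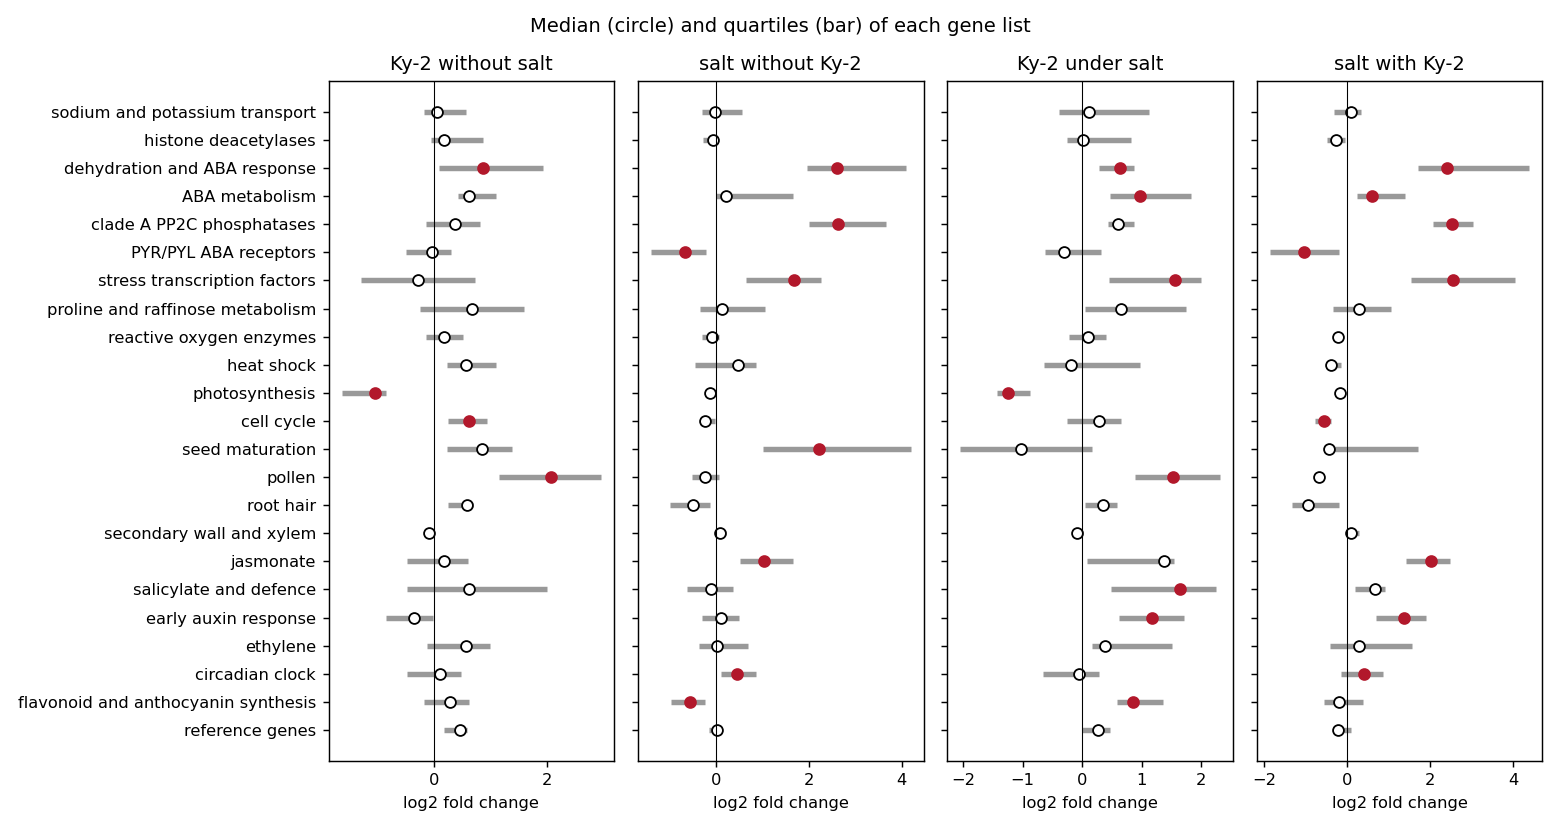
Median (circle) and quartiles (bar) of the log2 fold changes of the members of each of the 23 gene lists (horizontal axis, a separate scale per comparison), for the 4 comparisons of groups. Filled red circles mark lists with a camera adjusted p under 0.05 at the preset correlation. The dehydration and ABA response list lay at 2.61 for salt without Ky-2 and 2.4 with it, and the photosynthesis list at -1.04 for Ky-2 without salt and -1.26 under salt.

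The third comparison set Ky-2 plus salt against salt alone. AGO5 again had the largest fitted rise and was 183-fold higher, KNU at least 38.0-fold, KT5 at least 36.9-fold, AGL39 at least 26.5-fold, FLA20 at least 70.3-fold and PUM12 at least 39.8-fold. A further Argonaute, AGO9 (AT5G21150), was 67.9-fold higher, the MADS-box factor AGL43 (AT5G40220) at least 17.2-fold, the poly(A)-binding protein PAB5 (AT1G71770) at least 34.7-fold and the meiotic pairing gene PHS1 (AT1G10710) 47.6-fold (above background on 1 of 3 salt arrays). Small auxin up RNAs made up 8 of the 10 largest fitted falls among genes with a symbol, with SAUR22 at least 32.0-fold lower, SAUR19 (AT5G18010) 89.6-fold (above background on 1 of 3 Ky-2 plus salt arrays), SAUR27 (AT3G03840) at least 11.3-fold, SAUR23 at least 11.4-fold, SAUR63 (AT1G29440) 35.4-fold (above background on 1 of 3 Ky-2 plus salt arrays), SAUR20 (AT5G18020) 33.3-fold, SAUR24 (AT5G18080) 33.1-fold and SAUR28 (AT3G03830) 28.5-fold (above background on 1 of 3 Ky-2 plus salt arrays). NdhL was 104-fold lower and the transcription factor gene WRKY49 (AT5G43290) 22.9-fold. Without Ky-2 plus salt replicate 2, the only array of the group with SAUR19, SAUR63 and SAUR28 above background, the 3 were at least 59.0-fold, at least 51.0-fold and at least 14.9-fold lower. PHS1 was at least 28.3-fold higher without salt replicate 1 and 30.9-fold without salt replicate 2. These 20 genes had standard errors of 0.11 to 0.76 on the log2 scale and adjusted p of at most 3.0e-04. SAUR19 to SAUR24 are near-identical copies, so their probes may share signal. SOS1 rose by 1.15 ± 0.08 (adjusted p = 1.2e-06) and SOS3 by 0.44 ± 0.12 (adjusted p = 0.0074), to 1.89 ± 0.03 and -1.74 ± 0.07 (mean ± SD, n = 3). The SOS3 call ended on scan day 1 alone, and its adjusted p lay between 0.0017 and 0.1 over 28 alternatives.

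All 17 photosynthesis genes fell, with the same count adjusted over the list alone, LHCA1 at -1.93 ± 0.16 and LHCA4 (AT3G47470) at -1.1 ± 0.10. Photosynthesis genes had a median log2 change of -1.26 with camera adjusted p = 9.3e-06 and adjusted p = 0.52 with an estimated correlation. Dehydration and ABA response genes were again higher with Ky-2, and 14 of 23 measured rose, 1 fell and 8 did not pass (the same adjusted over the list alone), with the chloroplast cold protein genes COR15A at 3.45 ± 0.26 and COR15B (AT2G42530) at 2.25 ± 0.29. Dehydration and ABA response genes had a median log2 change of 0.64 with camera adjusted p = 0.0072 and adjusted p = 0.53 with an estimated correlation. Of the ABA metabolism genes, 7 of 10 measured rose and 3 did not pass (8 higher and 0 lower adjusted over the list alone), among them the synthesis enzymes NCED9 (AT1G78390, 2.4 ± 0.34) and AAO3 (AT2G27150, 0.81 ± 0.07) and the ABA 8'-hydroxylases CYP707A4 (AT3G19270, 1.93 ± 0.21) and CYP707A3 (AT5G45340, 1.55 ± 0.26). ABA metabolism genes had a median log2 change of 0.98 with camera adjusted p = 0.019 and adjusted p = 0.52 with an estimated correlation. Stress transcription factors were higher too, and 13 of 21 measured rose and 8 did not pass (the same adjusted over the list alone), DREB2C at 3.44 ± 0.37 and MYB74 (AT4G05100) at 1.74 ± 0.27. Stress transcription factors had a median log2 change of 1.56 with camera adjusted p = 0.0058 and adjusted p = 0.63 with an estimated correlation. Without salt replicate 3, Ky-2 plus salt replicate 1 or Ky-2 plus salt replicate 3, only 7 of these factors rose.

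Flavonoid genes rose with Ky-2 under salt, and 10 of 12 measured rose, 1 fell and 1 did not pass (the same adjusted over the list alone), with LDOX at 1.49 ± 0.11, the glycosyltransferase UF3GT (AT5G54060) at 1.33 ± 0.12 and the anthocyanin regulator MYB90 (AT1G66390) at 2.38 ± 0.32. The 1 fall passed only with all arrays or without untreated replicate 1, Ky-2 replicate 1 or 3 or salt replicate 2. Flavonoid and anthocyanin synthesis genes had a median log2 change of 0.85 with camera adjusted p = 0.0054 and adjusted p = 0.52 with an estimated correlation. Early auxin response genes rose as well, and 8 of 12 measured rose and 4 did not pass (the same adjusted over the list alone), with the conjugating enzymes DFL1 (AT5G54510) and WES1 (AT4G27260) at 1.71 ± 0.12 and 1.76 ± 0.18 and the repressors IAA5 (AT1G15580) and IAA19 (AT3G15540) at 2.19 ± 0.40 and 1.71 ± 0.32. IAA5 was at 1.6 without salt replicate 3. Early auxin response genes had a median log2 change of 1.17 with camera adjusted p = 0.0089 and adjusted p = 0.52 with an estimated correlation. Of the salicylate and defence genes, 7 of 11 measured rose, 1 fell and 3 did not pass (8 higher and 1 lower adjusted over the list alone), with NIMIN1 (AT1G02450) at 3.17 ± 0.43, PR5 (AT1G75040) at 2.68 ± 0.35 and the salicylate synthesis enzyme EDS16 (AT1G74710) at 1.76 ± 0.12. The 1 fall did not pass without salt replicate 2 or 3 or Ky-2 plus salt replicate 3. Salicylate and defence genes had a median log2 change of 1.65 with camera adjusted p = 0.033 and adjusted p = 0.52 with an estimated correlation. Of the pollen genes, 3 of 4 measured rose and 1 did not pass (the same adjusted over the list alone), TUA1 at 1.02 ± 0.08. Here too, ACT12 and BCP1 were in the test only because they were above background on Ky-2 arrays. Pollen genes had a median log2 change of 1.52, or 1.04 with dim members at their bounds, with camera adjusted p = 0.025 and adjusted p = 0.52 with an estimated correlation. The pollen call ended with normexp background correction (adjusted p = 0.398) and with normexp and quantile normalization (adjusted p = 0.0748), and the adjusted p lay between 0.017 and 0.52 over 19 alternatives.

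Limma called 15045 genes between Ky-2 plus salt and salt, 7265 higher and 7780 lower, and 5065 moved at least 2-fold, 2842 higher. The number past 2-fold was 3134 with normexp background correction, 3138 with normexp and quantile normalization and 3324 with the authors' processed values. The number called was 14548 with slide as a block, 15595 with scan day as a block and 12645 on scan day 1 alone. Slide 4 held replicate 3 of Ky-2 plus salt alone, so the slide block takes that array out of the comparisons that use it. With spike-in scaling and the replicate block, 83.1% of the calls were higher instead of 48.3%, and the median of all genes moved from -0.02 to 0.50. Replicate 3 of the salt group and replicate 2 of the Ky-2 plus salt group stood apart from their groups, and without both arrays 13923 genes were called.

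The fourth comparison gave the salt response of plants that had received Ky-2. BHLH92 was at least 117-fold higher, the jasmonate-inducible tyrosine aminotransferase TAT3 (AT2G24850) 344-fold and the cuticle regulator MYB41 (AT4G28110) at least 78.6-fold. Also higher were MYB15 (AT3G23250) at 271-fold (above background on 1 of 3 Ky-2 arrays), the cold response factor CBF1 (AT4G25490) 198-fold (above background on 1 of 3 Ky-2 arrays), the redox-responsive factor RRTF1 (AT4G34410) 195-fold (above background on 1 of 3 Ky-2 arrays), LEA4-5 202-fold, the methyltransferase FAMT (AT3G44860) 148-fold, HAI3 at least 36.5-fold and MYB102 at least 28.2-fold. Among the falls, SRO4 (AT3G47720) was 36.4-fold (above background on 2 of 3 Ky-2 plus salt arrays), SAUR28 23.3-fold (above background on 1 of 3 Ky-2 plus salt arrays) and LBD41 (AT3G02550), a factor gene induced by low oxygen, 23.1-fold lower. The methyl esterase MES13 (AT1G26360) was 16.1-fold (above background on 1 of 3 Ky-2 plus salt arrays) and the organic cation transporter OCT3 (AT1G16390) 14.6-fold (above background on 1 of 3 Ky-2 plus salt arrays) lower. SAUR27 was at least 4.0-fold lower, SAUR19 14.3-fold (above background on 1 of 3 Ky-2 plus salt arrays), SAUR75 (AT5G27780) 13.4-fold, SAUR63 12.4-fold (above background on 1 of 3 Ky-2 plus salt arrays) and bHLH39 12.8-fold (above background on 2 of 3 Ky-2 plus salt arrays). Without Ky-2 replicate 1, MYB15 was 142-fold, CBF1 103-fold and RRTF1 109-fold higher, and without Ky-2 replicate 2, where RRTF1 and CBF1 were then below background in their group, the 2 were at least 147-fold and at least 173-fold higher. Without Ky-2 replicate 3, MYB15 was at least 254-fold higher. Without Ky-2 plus salt replicate 2, RRTF1 was 346-fold higher, and SRO4 was 61.6-fold, LBD41 67.4-fold, MES13 10.4-fold, SAUR28 at least 12.2-fold, SAUR19 at least 9.41-fold and SAUR63 at least 17.9-fold lower. Without replicate 1 of that group SRO4 was 20.5-fold and LBD41 12.9-fold lower, and without replicate 3 LBD41 was 14.1-fold and MES13 at least 10.2-fold lower. These 20 genes had standard errors of 0.15 to 1.53 on the log2 scale and adjusted p of at most 0.01. SOS3 rose by 0.97 ± 0.12 (adjusted p = 1.9e-04) and SOS1, at -0.07 ± 0.08, did not pass (adjusted p = 0.48).

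All 23 dehydration and ABA response genes rose with salt in Ky-2 plants, with the same count adjusted over the list alone, among them LEA7 (AT1G52690, 6.0 ± 0.23), LTI65 (4.7 ± 0.14) and LTI30 (4.6 ± 0.14). Dehydration and ABA response genes had a median log2 change of 2.4, or 2.38 with dim members at their bounds, with camera adjusted p = 4.6e-21 and adjusted p = 0.13 with an estimated correlation. Of the PP2C phosphatases 8 of 9 measured rose and 1 did not pass (the same adjusted over the list alone), with HAI1 at 5.1 ± 0.20 and ABI1 (AT4G26080) at 2.53 ± 0.15. Clade A PP2C phosphatases had a median log2 change of 2.53 with camera adjusted p = 2.4e-10 and adjusted p = 0.13 with an estimated correlation. ABA receptors fell again, and 1 of 10 measured rose, 7 fell and 2 did not pass (the same adjusted over the list alone), with PYL4 at -2.54 ± 0.08 and PYL6 at -3.03 ± 0.11. PYR/PYL ABA receptors had a median log2 change of -1.03 with camera adjusted p = 0.0031 and adjusted p = 0.13 with an estimated correlation. In the ABA metabolism list 5 of 10 measured rose and 5 did not pass (the same adjusted over the list alone), NCED3 at 4.45 ± 0.36. ABA metabolism genes had a median log2 change of 0.61 with camera adjusted p = 0.0016 and adjusted p = 0.31 with an estimated correlation. Among stress transcription factors 19 of 21 measured rose and 2 did not pass (the same adjusted over the list alone), HB-7 at 3.31 ± 0.12 and ABF3 at 1.88 ± 0.06. Stress transcription factors had a median log2 change of 2.56 with camera adjusted p = 4.9e-14 and adjusted p = 0.31 with an estimated correlation.

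Jasmonate genes rose with salt in Ky-2 plants, and 18 of 19 measured rose and 1 did not pass (the same adjusted over the list alone), with the synthesis enzymes OPR3 (AT2G06050) and AOS (AT5G42650) at 2.03 ± 0.21 and 1.58 ± 0.20 and the repressor JAZ10 (AT5G13220) at 2.85 ± 0.39. Jasmonate genes had a median log2 change of 2.03, or 1.91 with dim members at their bounds, with camera adjusted p = 3.0e-10 and adjusted p = 0.38 with an estimated correlation. Early auxin response genes rose, and 9 of 12 measured rose and 3 did not pass (the same adjusted over the list alone), IAA5 at 3.56 ± 0.40 and IAA19 at 3.03 ± 0.32. Early auxin response genes had a median log2 change of 1.36, or 1.2 with dim members at their bounds, with camera adjusted p = 1.1e-05 and adjusted p = 0.31 with an estimated correlation. Cell cycle genes fell, and 11 of 13 measured fell and 2 did not pass (the same adjusted over the list alone), the B-type cyclin CYC1BAT (AT5G06150) at -0.85 ± 0.09, the replication helicase subunit MCM2 (AT1G44900) at -0.70 ± 0.07 and PCNA1 at -0.77 ± 0.06. Cell cycle genes had a median log2 change of -0.55 with camera adjusted p = 1.7e-04 and adjusted p = 0.13 with an estimated correlation. Of the clock genes 7 of 12 measured rose, 2 fell and 3 did not pass (the same adjusted over the list alone), PRR5 at 2.01 ± 0.12 and ELF4 (AT2G40080) at 1.71 ± 0.25. Circadian clock genes had a median log2 change of 0.41 with camera adjusted p = 0.016 and adjusted p = 0.19 with an estimated correlation. Without Ky-2 plus salt replicate 1, 4 of the clock genes rose. Only 1 fell without any 1 of the untreated replicates, Ky-2 replicate 1 or 2, salt replicate 2 or Ky-2 plus salt replicate 1 or 3. The sodium transporter HKT1 (AT4G10310) fell by 1.85 ± 0.18 on the log2 scale, and GolS2 rose by 6.4 ± 0.51.

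Salt changed 9277 genes in Ky-2 plants, 3526 higher and 5751 lower, and 2239 moved at least 2-fold, 1515 higher. The number past 2-fold was 1371 with normexp background correction, 1362 with normexp and quantile normalization and 1437 with the authors' processed values. The number called was 8171 with slide as a block, 10212 with scan day as a block and 5680 on scan day 1 alone. With spike-in scaling and the replicate block 4497 were called, 68.2% of them higher instead of 38.0%. Without the 2 arrays that stood apart 9711 were called, and LBD41 was at 5.2 on Ky-2 plus salt replicate 2 against 0.43 and 0.70 on replicates 1 and 3. The call of LBD41 ended on scan day 1 alone.

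Of the 23 lists, 9 were called in none of the 5 comparisons. For Ky-2 without salt, 5 of 10 measured rose, 2 fell and 3 did not pass (the same adjusted over the list alone) among the proline and raffinose genes, 6 of 16 measured rose, 3 fell and 7 did not pass (the same adjusted over the list alone) among reactive oxygen enzymes and 7 of 14 measured rose, 2 fell and 5 did not pass (the same adjusted over the list alone) among heat shock genes. In the same comparison 7 of 12 measured rose, 2 fell and 3 did not pass (the same adjusted over the list alone) among ethylene genes, 4 of 9 measured rose, 2 fell and 3 did not pass (the same adjusted over the list alone) among genes often used as references, and no root hair or secondary wall gene passed. The camera adjusted p was 0.26 for proline and raffinose, 0.5 for reactive oxygen, 0.091 for heat shock and 0.25 for ethylene. It was 0.18 for reference genes, 0.47 for root hair, 0.66 for secondary wall, 0.18 for histone deacetylases and 0.56 for ion transport. For salt in Ky-2 plants, 1 of 8 measured rose, 4 fell and 3 did not pass (the same adjusted over the list alone) among root hair genes.

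The last comparison asked whether Ky-2 changed the response to salt, the question in the title of the series. Log2 differences below are the salt response with Ky-2 minus that without. The response of CBF2 (AT4G25470), a cold and drought response factor, was larger with Ky-2 by 5.03 ± 1.13, that of the expansin-like EXLA3 (AT3G45960) by 4.92 ± 0.74, of the ethylene response factor ERF104 (AT5G61600) by 3.83 ± 0.71, of MYB41 by 3.4 ± 0.42 and of MYB39 (AT4G17785) by 3.3 ± 0.30. Ethylene synthesis enzymes also had positive differences, ACS8 at 4.72 ± 0.80, ACS11 (AT4G08040) at 3.31 ± 0.61 and ACS4 at 3.29 ± 0.34. ACS4 had fallen with salt without Ky-2, so its positive difference does not stand for a larger rise. The ethylene list as a whole was not called in the interaction (camera adjusted p = 0.95), with 2 of 12 measured higher, 2 lower and 8 not past the threshold. The response was smaller, or went further down, for TSPO (-4.83 ± 0.18), the malic enzyme NADP-ME1 (AT2G19900, -3.7 ± 0.27), the transporter UMAMIT19 (AT1G21890, -3.34 ± 0.28), DIN2 (-3.21 ± 0.28), AACT1 (-3.13 ± 0.65), SAUR28 (-4.08 ± 1.07), SAUR19 (-3.68 ± 0.82) and SAUR27 (-3.65 ± 0.46). ACS8, ACS4, MYB41, NADP-ME1, SAUR27, UMAMIT19 and DIN2 were below background in at least 1 group, so their differences are fitted values and not bounds. TSPO, DIN2 and AACT1 had already risen with Ky-2 alone and ACS8 had fallen, so their salt responses started from other levels. Neither SOS gene differed detectably in its response to salt, SOS1 at -0.29 ± 0.11 (adjusted p = 0.15) and SOS3 at -0.06 ± 0.17 (adjusted p = 0.89).

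Some of these calls lay near the threshold and ended when 1 array was left out. Leaving out any 1 array except Ky-2 plus salt replicate 2 ended the call of SAUR28 (adjusted p between 0.0641 and 0.113). The call of SAUR19 ended (0.0509 to 0.0696) without untreated replicate 1 or 2, Ky-2 replicate 1 or 2, salt replicate 2 or 3, or Ky-2 plus salt replicate 1 or 3. That of CBF2 ended (0.0565 to 0.0727) without replicate 1 or 2 of Ky-2, 1 or 3 of salt, or 1 or 3 of Ky-2 plus salt, and that of AACT1 (0.0521 to 0.0573) without Ky-2 replicate 1 or 2, salt replicate 1 or Ky-2 plus salt replicate 3. Other differences moved but stayed called. Without untreated replicate 1, CBF2 was at 3.98, EXLA3 at 4.26 and ERF104 at 3.22, and without untreated replicate 3 CBF2 was at 5.68. ACS8 was at 4.12 without salt replicate 3. Without Ky-2 plus salt replicate 2, SAUR28 was at -5.09 and SAUR19 at -4.43. Normexp background correction ended the calls of 6 of the 16 genes, namely ACS8, SAUR19, SAUR27, SAUR28, UMAMIT19 and DIN2. With it DIN2 turned to 0.21 (adjusted p = 0.495), and its adjusted p lay between 2.8e-04 and 0.84 over 27 alternatives. Of the 16 genes, 9 stayed called with slide as a block and 3 on scan day 1 alone.

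The early auxin list had the smallest camera p of the interaction, and 6 of 12 measured were higher and 6 did not pass (9 higher and 0 lower adjusted over the list alone), with IAA5 at 3.0 ± 0.56, IAA19 at 2.67 ± 0.46 and IAA6 (AT1G52830) at 2.05 ± 0.30. The calls of IAA5 and IAA19 ended with slide as a block, and that of IAA6 with normexp background correction. IAA5 was at 2.41 without salt replicate 3. Early auxin response genes had a median log2 change of 1.08 with camera adjusted p = 8.3e-08 and adjusted p = 0.19 with an estimated correlation. The stress transcription factor list shifted up in the interaction, and 3 of 21 measured were higher, 1 were lower and 17 did not pass (7 higher and 1 lower adjusted over the list alone), DREB2B being the 1 that was lower, at -1.65 ± 0.20. Stress transcription factors had a median log2 change of 0.98 with camera adjusted p = 4.7e-04 and adjusted p = 0.54 with an estimated correlation. The median was 2.48 on slide 1 and 0.01 on slide 2, and 0.60 without untreated replicate 1. Without Ky-2 plus salt replicate 2, 5 of them were higher, and without salt replicate 3, 2 were lower. The cell cycle list shifted down, and 3 of 13 measured were lower and 10 did not pass (0 higher and 7 lower adjusted over the list alone), CYC1BAT at -0.86 ± 0.13. Cell cycle genes had a median log2 change of -0.31 with camera adjusted p = 4.7e-04 and adjusted p = 0.13 with an estimated correlation. Of the flavonoid genes 1 of 12 measured were higher and 11 did not pass (8 higher and 0 lower adjusted over the list alone). Flavonoid and anthocyanin synthesis genes had a median log2 change of 0.54 with camera adjusted p = 1.7e-04 and adjusted p = 0.51 with an estimated correlation. Without Ky-2 plus salt replicate 2, 6 of them passed, and 0 passed without any other array except salt replicate 3.

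In the jasmonate list 2 of 19 measured were higher, 1 were lower and 16 did not pass (5 higher and 2 lower adjusted over the list alone), OPR3 at 1.55 ± 0.29. The call of OPR3 ended with slide as a block and with spike-in scaling and the replicate block. Jasmonate genes had a median log2 change of 1.42 with camera adjusted p = 0.014 and adjusted p = 0.64 with an estimated correlation. The median was 0.62 without untreated replicate 1 and 0.93 without salt replicate 3. The list call ended with slide as a block (0.132) and without untreated replicate 1 (0.0675), salt replicate 3 (0.110) or Ky-2 plus salt replicate 1 (0.0714), and its adjusted p lay between 2.9e-04 and 0.64 over 19 alternatives. When single arrays were left out, 4 members passed as higher without salt replicate 2 or Ky-2 plus salt replicate 2, and 1 without any other array. Of the salicylate and defence genes 2 of 11 measured were higher and 9 did not pass (3 higher and 0 lower adjusted over the list alone), PAD4 (AT3G52430) at 1.3 ± 0.19. Only 1 passed without untreated replicate 1, 2 or 3, Ky-2 replicate 1, salt replicate 1 or Ky-2 plus salt replicate 1. Salicylate and defence genes had a median log2 change of 0.93 with camera adjusted p = 0.0065 and adjusted p = 0.42 with an estimated correlation. Its median was 0.61 without salt replicate 3. On slide 2 the medians of the jasmonate and the salicylate and defence lists went the other way, at -0.53 and -0.50, while the other 33 of the 35 list calls of all comparisons kept the sign of their median on every slide that held the groups compared (slides 1 to 3 for the 2 comparisons with untreated plants, slides 1 and 2 for the others), that of the stress transcription factors only at 0.01. With slide as a block 34 lists were called in all, and each of the 35 medians kept its sign on both scan days. Among genes of lists that were not called, the dehydration genes KIN2 (-1.6 ± 0.11) and LTI65 (-1.6 ± 0.20) rose less with salt in Ky-2 plants, and the ion transporters CAX3, NHX2 and HKT1 differed by 1.97 ± 0.27, -0.64 ± 0.09 and -1.54 ± 0.25. KIN2 had already risen with Ky-2 without salt, so its smaller response started from a higher level. The call of LTI65 ended with the authors' processed values, those of NHX2 and CYC1BAT with spike-in scaling and the replicate block, and the adjusted p of LTI65 lay between 0.0012 and 0.73 over 28 alternatives. Of the 12 list members named for the interaction, 3 (KIN2, IAA5 and IAA19) stayed called on scan day 1 alone.

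The interaction was called for 1684 genes, 871 higher and 813 lower, and 666 differed at least 2-fold, 419 higher. The number past 2-fold was 436 with normexp background correction, 407 with normexp and quantile normalization and 438 with the authors' processed values. That number was 439 without untreated replicate 2, 399 and 414 without Ky-2 replicate 1 and 2, 433 without salt replicate 3, and 389, 1028 and 354 without Ky-2 plus salt replicate 1, 2 and 3. It was 344 with slide as a block, 372 with spike-in scaling and the replicate block, and 1061 with array weights. The number called was 819 with slide as a block, 1981 with scan day as a block and 37 on scan day 1 alone. With spike-in scaling and the replicate block 409 were called, 66.0% of them higher instead of 51.7%. The count moved with single arrays, from 756 without Ky-2 plus salt replicate 3 to 2685 without Ky-2 plus salt replicate 2, and was also below 1684 by over 1.5 times without untreated replicate 2 (825) or 3 (1097), Ky-2 replicate 1 (844) or 2 (853), salt replicate 1 (954) or 3 (916), or Ky-2 plus salt replicate 1 (821). Without salt replicate 3 and Ky-2 plus salt replicate 2 together it was 1805.

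Most genes that Ky-2 raised or lowered without salt did so under salt as well, in comparisons that share no arrays. Of the 7188 genes higher with Ky-2 without salt, 5720 were also higher under salt, where independent lists would share 2226, and of the 7765 lower genes 6286 were also lower, against 2575. Only 58 and 178 went the opposite way. For the 2 salt comparisons, 1936 genes rose in both (495 for independent lists) and 2886 fell in both (1101), while 79 and 101 went opposite ways. Across genes, which are not independent replicates, the Ky-2 effects correlated at r = 0.849 (rho 0.808) and the salt effects at r = 0.708 (rho 0.590). The average Ky-2 effect and the average salt effect correlated at r = 0.108 across genes, with a jackknife SE of 0.0589 over arrays. Of 100 relabellings of the arrays, 73 gave a correlation as large in size, with a median size of 0.236 and a maximum of 0.869. Relabelled contrasts still held the real effects of both treatments, so they could not decide whether the 2 effects run together, and this was not shown. The correlation of the real effects was 0.0614 on scan day 1 and 0.164 on scan day 2.

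**Figure D3:**
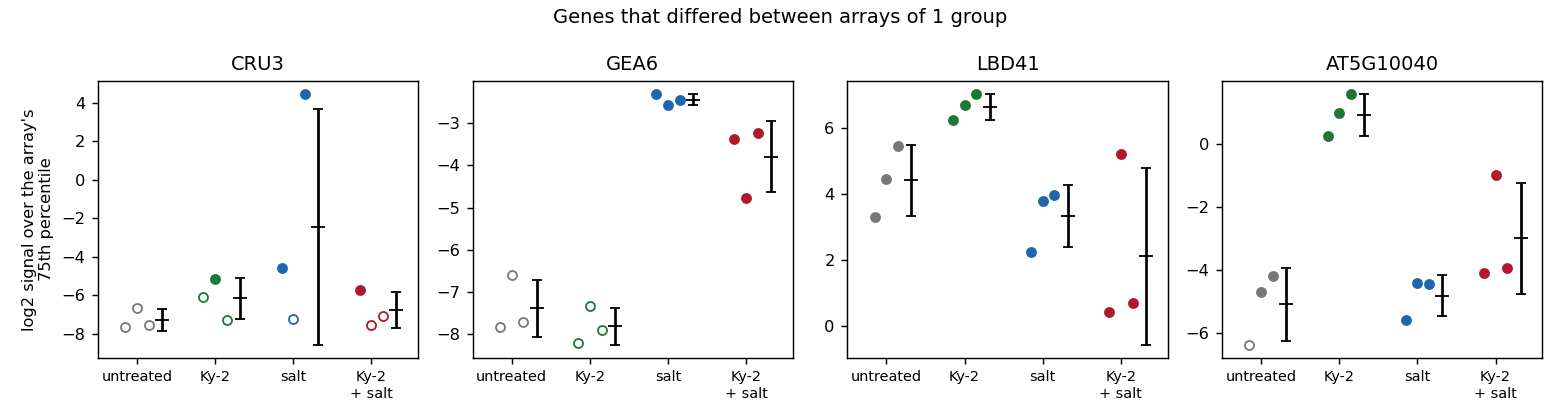
Signal of CRU3, GEA6, LBD41 and AT5G10040 on each of the 12 arrays, as log2 over the 75th percentile of the array (vertical axis), by group (horizontal axis), with open points for arrays not well above background and bars for the mean and SD of 3 arrays. CRU3 was at 4.48 in salt replicate 3 and at most at -4.56 elsewhere, while GEA6 was higher on all salt arrays.

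**Figure D4:**
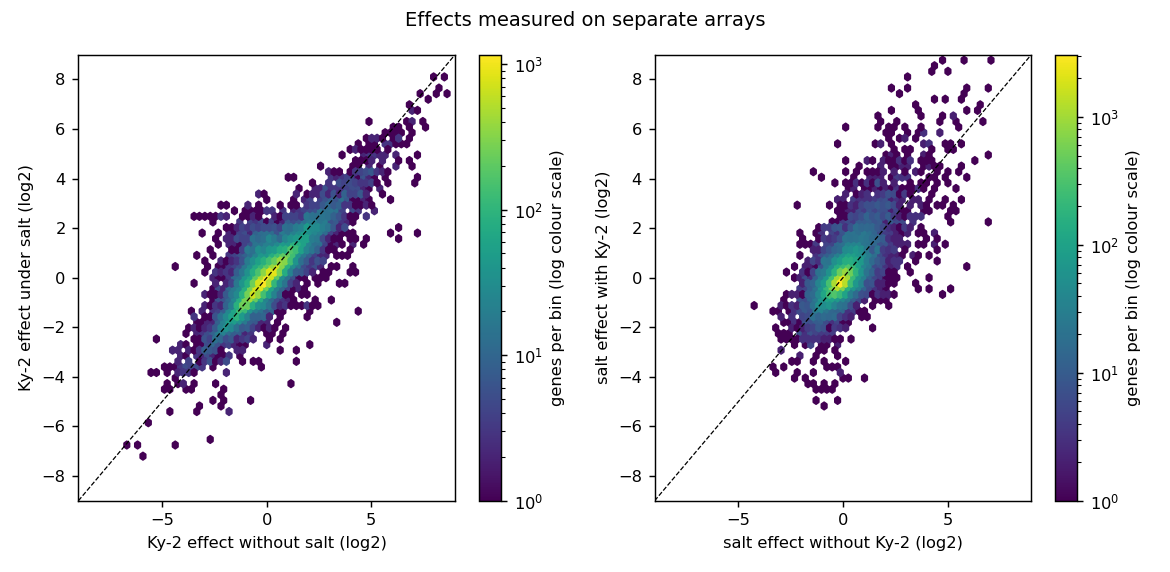
Log2 effects of 23459 genes in pairs of comparisons that share no arrays, as counts of genes per bin (colour, log scale). The left panel sets the Ky-2 effect under salt (vertical) against that without salt (horizontal), r = 0.849, and the right panel the salt effect with Ky-2 (vertical) against that without (horizontal), r = 0.708; the dashed line marks equal effects.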

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

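The tests on the groups of genes and arrays that stood apart were chosen after those results were seen, except that 8 further seed genes and 12 further pollen genes were fixed before their values were seen, and the counts of other splits of the arrays were fixed before.

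The salt response of single genes differed with Ky-2, by limma's test of the interaction (adjusted p under 0.05, log2 difference of responses, n = 3 per group). Among called genes with a symbol, the largest positive fitted differences were those of CBF2 (5.03), EXLA3 (4.92), ACS8 (4.72), ERF104 (3.83), MYB41 (3.4), ACS11 (3.32), MYB39 (3.3) and ACS4 (3.29). The largest negative ones were those of TSPO (-4.83), SAUR28 (-4.08), NADP-ME1 (-3.7), SAUR19 (-3.68), SAUR27 (-3.65), UMAMIT19 (-3.34), DIN2 (-3.21) and AACT1 (-3.13). Of these 16 genes, 12 stayed called whichever array was left out, and 10 with normexp background correction. With slide as a fixed block 9 stayed called, and 3 on scan day 1 alone. Some were below background in a group. TSPO, DIN2 and AACT1 were already raised by Ky-2 alone and ACS8 was lowered by it, so their salt responses started from other levels. Among list members, IAA5 differed by 3.0, IAA19 by 2.67, IAA6 by 2.05, OPR3 by 1.55, PAD4 by 1.3, NHX2 by -0.64 and DREB2B by -1.65. KIN2 differed by -1.6, LTI65 by -1.6, CAX3 by 1.97, HKT1 by -1.54 and CYC1BAT by -0.86. DREB2B and KIN2 had already risen with Ky-2 alone.

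Of the 23 lists, 6 shifted in the interaction by camera at the preset correlation. Their median log2 differences were 0.98 for stress transcription factors, -0.31 for cell cycle genes, 1.42 for jasmonate genes, 0.93 for salicylate and defence genes, 1.08 for early auxin response genes and 0.54 for flavonoid genes. None of these calls held with an estimated correlation, where the smallest adjusted p over all 115 list tests was 0.127.

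Probes that the array design does not name by a locus were in no comparison of the report. Of 8473 such probes above background, limma called 2637 for Ky-2 without salt, 837 for salt without Ky-2, 2651 for Ky-2 under salt, 940 for salt with Ky-2 and 61 for the interaction.

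Other splits of the same arrays called far fewer genes. Among the 10 splits of the 6 arrays of each comparison, 1, the real one, gave as many calls, at 14953 against 0 for the highest other split for Ky-2 without salt and 7785 against 2 for salt without Ky-2. For Ky-2 under salt the real split gave 15045 against 1, and for salt with Ky-2 9277 against 1. With 10 splits the share cannot fall under 0.05. For the interaction, 1 of 100 splits, the real one, gave as many, 1684 against at most 5, and so it was, against at most 38, when labels were exchanged only among arrays of the same replicate number, a test added later. No other labelling drawn for these arrays came near the real count. Every other split of 6 arrays mixed the 2 groups compared, so any real difference widened the spread within its sides and kept its count low. Low counts there are therefore no separate evidence for the real count. The splits cannot exclude chance differences between cultures, since nothing in the labels shows that the replicates were separate cultures. Only the 2 main effects were subtracted beforehand, so the interaction stayed in the data and may have lowered the counts of the other splits. The interaction count was 1981 with scan day as a block and 2693 with slide as a random block, which keep all arrays, and 819 with slide as a fixed block and 37 on scan day 1 alone, which do not.

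Both sets of Ky-2 arrays showed RNAs that were below background elsewhere, and 316 of the genes tested were above background on all 6 Ky-2 arrays and on no other, against 36 with the reverse pattern. Brighter Ky-2 arrays were excluded as the cause, since the lower quartile of the unscaled log2 rise, with dim arrays at their bounds, was 1.42 and the largest difference in the 75th percentile between any 2 arrays was 0.789, which 305 of the 316 exceeded. Pollen RNA in the samples may contribute and could not be judged, since 7 of 12 further pollen genes outside the lists were above background on all 6 Ky-2 arrays, where at least 9 had been set as needed and under 6 as excluding it. A first test, on VGD1, PPME1 and PGA4 (above background on at most 1 Ky-2 array), was replaced as void because it left out list members that rose, and of the 7 pollen genes AGP6, sks13 and AT5G07430 were above background on all other arrays too. AGP11, AGP23 and AT1G29140 had clearly higher means on the Ky-2 arrays. By contrast, sks13 was lower there (-3.75 against -0.83), as was AT5G07430, and AT5G45880 hardly differed. Of the remaining genes, FLA3 was above background on 6 other arrays and 0 Ky-2 arrays. No array showed sks11, ANX1, ANX2 or APPB1 above background. A derepression of silent genes by the inhibitor may account for the pattern and was not tested.

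Salt replicate 3 held seed storage RNAs at levels far above those of the other arrays, with the cruciferin CRU3 at 4.48 and 524-fold above the highest other array. These levels were not shared by the salt group, since 9 of 10 storage genes were at least 4-fold above both other salt arrays and the median log2 difference was 5.39. That count restates the pattern, because it was seen in the same genes. A weaker response shared by the group could not be excluded. In salt replicate 1, OLEO1 was at -2.62 and OLEO2 at -1.44, against at most -6.11 and -7.2 on untreated arrays. Both genes were below background in salt replicate 2. RNA from seed tissue in that sample may be the source but was not settled, since a first test on those 10 genes, replaced as void, only restated the pattern and 5 of 8 further seed genes outside the lists were above background there and at least 4-fold above every other array, where 6 had been set as the number needed. Of those 8, the vicilin gene PAP85 was at 0.31 against at most -6.40 elsewhere, OLEO3 was below background on every array, and AT3G01570, ATS1, AT2G28490 and HSD1 were above background on 11, 8, 3 and 1 of the other arrays. No biological explanation was tested.

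Ky-2 plus salt replicate 2 stood apart from its group in a low-oxygen gene set, whose median signal was 1.93 there, 0.32 and 0.54 in replicates 1 and 3, and between 2.31 and 3.13 on the Ky-2 arrays. An exchange with a Ky-2 array was excluded, since its slope on the salt effect was 0.798 (0.90 and 0.87 for the other replicates) and no Ky-2 array exceeded 0.0722. A uniformly smaller response to salt in replicate 2 was not settled as the source of the difference. Its share was 0.862 for genes that rise and 1.15 for the 33 genes that fall. The bootstrap interval for the falling genes, 1.03 to 1.31, lay above 1, where a uniformly smaller response would put it below 1. That interval measures the spread between genes and not between arrays. The 2 shares were also apart in replicates 1 and 3, where that of genes that rise was the higher. A mixture with Ky-2 RNA may account for the difference and could not be judged. Genes higher with salt called for 31.4% and genes lower with salt for -1.79%. These 2 estimates were also apart in replicate 1 (-27.0% and -0.420%) and replicate 3 (-9.51% and 1.85%). The genes for the shares and mixtures were changed after a first choice, made on replicates 1 and 3 of the group and so biased to shares below 1, gave shares of 0.778 and 0.683 and mixtures of 43.7% and 12.7%. A difference in the oxygen supply of that sample may account for it and was not tested.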

How the results depend on the processing

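Scan day, spike-in scaling and the joint omission of salt replicate 3 and Ky-2 plus salt replicate 2 were chosen after seeing the data, the other alternatives before, except that leaving out arrays and the slide block were added later for the lists. The interaction count moved most: 1684 became 902 with no filter on dim probes, 3482 with array weights, 2693 with slide as a random block, 819 with slide as a fixed block, 37 on scan day 1 alone and 409 with spike-in scaling and the replicate block. Salt calls fell to 4602 without Ky-2 and 5680 with Ky-2 on scan day 1 alone, and to 3937 and 4497 with spike-in scaling and the replicate block together, where the block alone raised them. Leaving out 1 array gave 13581 to 15217 calls for Ky-2 without salt, 5738 to 8158 for salt without Ky-2, 13647 to 15063 for Ky-2 under salt, 6932 to 9646 for salt with Ky-2 and 756 to 2685 for the interaction, a correlation of the effects of 0.0841 to 0.146, and 35 to 38 list calls. With an estimated correlation 0 lists were called. Apart from that, 3 of the 35 list calls were lost in at least 1 of the 19 alternatives run for the lists. Those did not include scan day, spike-in scaling, array weights, the filters on dim probes, the authors' processed values or slide as a random block. Whether the list calls hold under these is therefore not known. The causes were not tested, except that scan day 1 alone leaves 8 arrays.

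The replicate numbers were not taken to pair the samples, since only 11 of 18 pairs of arrays with the same number correlated above 0.1 after group means were removed and the lowest was at -0.06, although 11 of 12 arrays correlated best with their own number. With the replicate block the counts were 15951, 9096, 16077, 10968 and 2362, in the order of the comparisons, all above those of the main fit, and 35 lists were called.

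The rule for named genes gives 453 pairs of a gene and a comparison, of which 329 kept their direction and side of the threshold under every alternative run for them, 119 lost a call in at least 1 and 6 turned in at least 1. The text names 209 of them, of which 177 kept both, and list members that had lost a call under an alternative were in part passed over, so the larger set is the fairer measure. Among those named, the interaction of DIN2 turned to 0.214 with normexp and 0.0846 with normexp and quantile normalization. That of SOS3, near 0 and not called, turned to 0.0717 with normexp, 0.0181 with normexp and quantile normalization, 0.0115 with array weights and 0.0724 with spike-in scaling and the replicate block, and ran from -0.176 to 0.0197 when single arrays were left out. SOS1, in salt with Ky-2, turned to 0.0725 with spike-in scaling and the replicate block. The mean of all detected probes of a gene was not run, since each locus has 1 probe. Signal over background limits the values of genes that were dim in a group, for which folds are bounds.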

Other observations

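The gene groups below were chosen after the results were seen, their tests included, and no call among them held with an estimated correlation.

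Of 26 genes of the low-oxygen response 22 rose with Ky-2 without salt (median log2 change 2.08, adjusted p = 7.2e-06 by camera over all groups tested after the results were seen, adjusted p = 0.46 with an estimated correlation). Among the 18 members not seen before the group was written, 17 rose, with a median of 1.7. Under salt 8 of the 26 rose with Ky-2 (median 0.34, adjusted p = 0.18, adjusted p = 0.85 with an estimated correlation), and without Ky-2 plus salt replicate 2, 7 rose and 5 fell, with a median of -0.08. Of the 18 members 8 rose under salt, with a median of 0.55 (adjusted p = 0.042, adjusted p = 0.67 with an estimated correlation). With salt in Ky-2 plants 15 of the 26 fell (median -1.49, adjusted p = 7.9e-04, adjusted p = 0.66 with an estimated correlation), and 19 fell without Ky-2 plus salt replicate 2. In the interaction 7 were lower (median -1.85, adjusted p = 2.3e-08, adjusted p = 0.46 with an estimated correlation), and 19 without that array. The 18 members, which are part of the 26, had medians smaller in size, a difference that was not tested. For salt in Ky-2 plants 7 of them were lower (median -0.75, adjusted p = 0.032, adjusted p = 0.67 with an estimated correlation). In the interaction 6 of them were lower (median -1.24, adjusted p = 5.0e-07, adjusted p = 0.46 with an estimated correlation).

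Among 18 genes with an Ndh or Pns symbol, subunits of the chloroplast NADH dehydrogenase-like complex, 16 fell with Ky-2 without salt and 17 under salt (medians -1.73 and -1.85, adjusted p = 5.0e-07 and 2.0e-07, adjusted p = 0.46 with an estimated correlation in both). Of 16 small auxin up RNA genes 11 fell with Ky-2 without salt and 13 under salt, and 10 fell with salt in Ky-2 plants (medians -1.94, -4.66 and -1.94, adjusted p = 0.013, 3.4e-04 and 1.7e-04, adjusted p = 0.67, 0.46 and 0.46 with an estimated correlation).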
